A study of Arabidopsis thaliana with 16 samples.

How the data were processed

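RNA from germinating Arabidopsis seeds was hybridised to 16 Affymetrix arrays, 4 for each combination of genotype (wild type or the pkl mutant) and treatment (with or without uniconazole-P). Each array was placed in its group by its title, and the number in the title (1 to 4) served as its name. The labels do not say that the 4 arrays of a group came from separate seed cultures, so p-values measure only the spread between these samples, which may be technical. The dose, the time of harvest and the growth conditions were not given in the sources used here.

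The values deposited by the authors were 1 intensity per probe set and array, on a linear scale and in whole numbers. Between 17.2% and 22% of the values of an array lay below 0, as happens after background subtraction. The mean of each array, after the lowest and highest 2% of probe sets were dropped, was 1002, and these means differed by at most 0.04% between arrays, so the deposited intensities had been scaled to a common level. This is read from the values themselves, and the software was not given in the sources used here. The lowest value, -105115, stood alone (the next was -2706) and was absorbed by the floor described next.

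The intensities were scaled to a common trimmed mean, set to a floor of 57 where they lay below it (the 30th percentile of all values), and then converted to log2. Of 8297 probe sets, 50 controls were left out, and 6749 were tested because they lay above the floor on at least 4 of the 16 arrays. From 27.6% to 31.5% of the probe sets of an array were at the floor. A fold change is therefore on the floored scale and understates the change of dim genes. Where every array of a group was at the floor, the fold is given as a lower bound ("at least"). Group means and SDs are of the scaled intensities before the floor, in arbitrary units, and can be negative. The number of arrays, 4 per group, limits the precision.

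Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2-sided). A single fit with 4 group means covered 5 comparisons: pkl against wild type without and with uniconazole, uniconazole in wild type and in pkl, and the interaction, which is the uniconazole effect in pkl minus that in wild type. A probe set passed when its Benjamini-Hochberg adjusted p was under 0.05 over all 6749 tested. Errors of log2 fold changes are standard errors from this fit. Gene lists with at least 2 tested members were compared with the other genes by limma's camera, with the preset correlation of 0.01 and again with an estimated correlation, adjusted over the 8 lists within a comparison. Counts "adjusted over the list alone" apply the same threshold to the list's members only.

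Probe sets were named from GEO's platform annotation, which can be old, and symbols were updated by Entrez ID against RefSeq genes of the assembly TAIR10.1. The annotation gave 1 gene for 3794 probe sets and several for 70, and 4383 others apart from controls had no name here. Of the 3794, 3784 were found in RefSeq and 10 were not. Among tested probe sets, 3083 (45.7%) had 1 gene, standing for 2943 distinct genes, 51 had several and 3615 had none. No genome sequence was used, and the probes were not placed on it.

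The settings, the gene lists, the first set of alternatives and the rule for named genes were fixed before the data were examined. For both genotype comparisons and for uniconazole in wild type, the rule took the 8 higher and 8 lower genes of largest log2 fold change among probe sets with 1 gene that passed and whose groups did not overlap, every array of one group lying above every array of the other. For uniconazole in pkl and the interaction it took 4 each way, without the demand on overlap for the interaction. It added up to 3 passing members of each list, with the smallest p, and always PKL, LEC1, LEC2, FUS3, ABI3, PHE1 and GA3 where they had a probe set. If no gene passed, the 4 of smallest p were named as not passing. The probe set with the highest mean stood for a gene with several, and others are mentioned where they differ in call or sign. Genes outside the rule are named as chosen after their values were seen.

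The lists were embryo identity regulators, seed storage and oil body proteins, late embryogenesis abundant (LEA) proteins and dehydrins, abscisic acid (ABA) metabolism and ABA or cold response, gibberellin metabolism, gibberellin signalling and GASA genes, expansins and xyloglucan endotransglucosylases, photosynthesis, lipid mobilisation and glyoxylate cycle, cell cycle and DNA replication, heat shock proteins, auxin response, brassinosteroid synthesis and perception, ethylene synthesis and signalling, phenylpropanoid and flavonoid synthesis, Polycomb group and CHD3 chromatin factors, floral and meristem homeotic genes, root and root hair markers, and endosperm and seed coat markers.

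The alternatives were no further scaling, quantile normalization, floors at the 20th (intensity 5) and 45th percentile (162), no filter on dim probe sets, a filter at 8 arrays, no intensity trend, the array number as a block, only the 2 groups compared in the fit, limma's array weights, 1 probe set per gene, the statistic without moderation, a demand of at least 2-fold, and each array left out in turn. A further 3 were chosen after seeing the data: wild type array 3 and pkl array 4 left out together, the 4 arrays numbered 2 left out, and a floor at the 70th percentile (650).

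A genotype score placed each array on a line from 0 (the mean of wild type with uniconazole) to 1 (the mean of pkl with uniconazole) over the probe sets that passed between those groups. For an array of those groups the probe sets and means were found again without it.

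The limma fit was tried on simulated log2 values, with 200 of 6749 probe sets changed, 50 at each fold size. Values were drawn independently for each probe set from a normal distribution with its mean and spread. The scaling, floor and filter were not applied to them. They held no correlation between probe sets and no array between the genotypes, so the shares below need not hold for the real arrays. The shares also depend on the 200 changes: with fewer changes the adjusted threshold is stricter and a smaller share would pass. Simulating pkl against wild type without uniconazole, 18% of the 1.5-fold, 42% of the 2-fold, 84% of the 4-fold and 100% of the 8-fold changes passed, and 6.2% of the calls were false. For uniconazole in wild type these shares were 16%, 50%, 88% and 100%, with 4.5% false calls. For the interaction they were 8%, 20%, 56% and 82%, with 3.5% false calls.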

Results

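Transcript levels were measured in germinating seeds of Arabidopsis thaliana. The pkl mutant lacks normal function of PICKLE, a CHD3 chromatin remodelling factor that acts during germination to keep genes of the embryo programme repressed. Uniconazole-P is an inhibitor of gibberellin synthesis, and gibberellin promotes germination. The design asks how the 2 genotypes differ with and without the inhibitor, how each genotype responds to it, and whether these responses differ. There were 4 arrays in each of 4 groups (wild type, wild type with uniconazole, pkl, pkl with uniconazole), and 6749 probe sets were tested. Levels are given as mean scaled intensity ± SD (n = 4), and changes as log2 fold change ± SE with limma's adjusted p.

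The mutated gene could not be used to check the labels, because none of the named probe sets belonged to PKL. The embryo regulators LEC1, LEC2, FUS3 and ABI3, and the gibberellin synthesis gene GA3, had no named probe set either and were not analysed here. PHE1, a MADS-box gene of the endosperm, was above the floor on only 2 of 16 arrays, with means of -91.2 in wild type and -27.5 in pkl, and was not tested. The seed coat gene BAN and the cold-response gene COR15B were above the floor on 0 arrays.

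On the genotype score, in which 0 is wild type and 1 is pkl with uniconazole present in both, most arrays lay close to others of their own genotype. Untreated wild type arrays 1, 2 and 4 scored 0.08, 0.16 and 0.05, and pkl arrays 1, 2 and 3 scored 0.91, 0.86 and 0.87. Wild type array 3 scored 0.56 and pkl array 4 scored 0.49. With uniconazole the wild type arrays scored 0.07 to 0.27 and the pkl arrays 0.85 to 0.98. Along the first principal component (17% of the variance), wild type array 3 lay at 4.0 and pkl array 4 at -4.1. The other untreated wild type arrays lay between -18.7 and -16.9, and the other untreated pkl arrays between 18.5 and 21.5. Correlations between arrays ranged from 0.911 to 0.973, and the array most similar to pkl array 4 was wild type array 3 (r = 0.955 across probe sets). Wild type array 3 was itself most similar to wild type array 4 (r = 0.967).

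**Figure D1:**
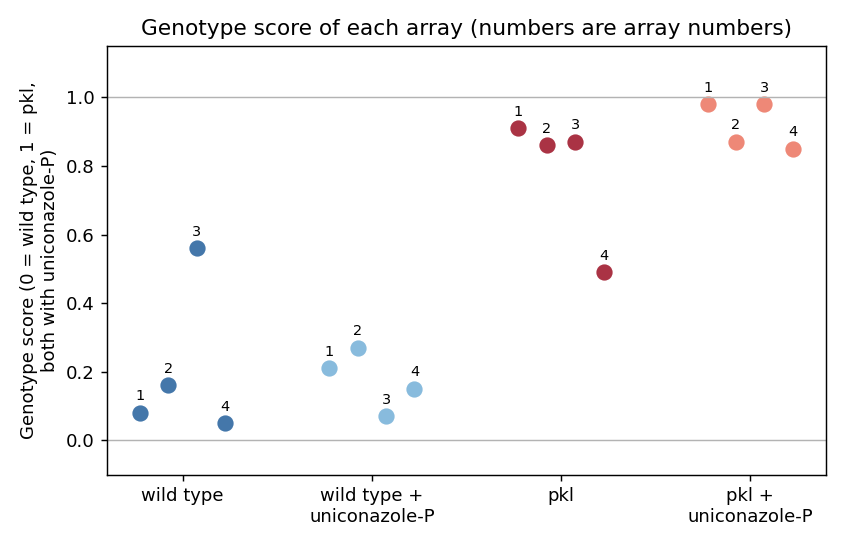
Genotype score of each of the 16 arrays (vertical axis, no unit, 0 for wild type and 1 for pkl with uniconazole), by group, each point 1 array with its number. Wild type array 3 at 0.56 and pkl array 4 at 0.49 lie apart from the other 3 arrays of their groups.

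Without uniconazole, a small heat shock protein gene, AT1G53540, rose from 32.5 ± 89.2 in wild type to 479.5 ± 111 in pkl (log2 2.68 ± 0.43, adjusted p = 0.0124), with 3 of the 4 wild type arrays at the floor. PRK, which encodes the Calvin cycle enzyme phosphoribulokinase, was at the floor on all wild type arrays and reached 285 ± 131 in pkl, at least 4.56-fold higher (2.19 ± 0.41, adjusted p = 0.014). AT1G62480 rose from 624.8 ± 522 to 2029 ± 582 (2.05 ± 0.38, adjusted p = 0.014), and AT1G62500 from 302.8 ± 85.1 to 653.5 ± 110.0 (1.14 ± 0.25, adjusted p = 0.0269). XTH33, of a family of enzymes that remodel xyloglucan in the cell wall, rose 2.16-fold (1.11 ± 0.27, adjusted p = 0.0432). Smaller rises were found for AT4G20860 (0.99 ± 0.23), AT1G09750 (0.96 ± 0.18) and AT2G25980 (0.72 ± 0.16), with adjusted p of 0.0396, 0.014 and 0.0318. A further probe set of AT4G20860 did not pass (0.63, adjusted p = 0.491). The genes that fell and did not overlap between groups were AT2G44220 (-1.67 ± 0.39, with 3 of 4 pkl arrays at the floor), AT1G54730 (-1.43 ± 0.34) and AT4G25170 (-0.73 ± 0.15), with adjusted p of 0.0375, 0.0411 and 0.0204.

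Among the lists in this comparison, 1 of 3 heat shock genes rose (2 adjusted over the list alone). The median change was 1.41 and all 3 were positive (camera adjusted p = 0.00422, and adjusted p = 0.11 with an estimated correlation). ATHSP22.0, among these 3, lay near the floor in wild type (mean log2 6.07) and in pkl (6.23). It differed by 0.16 ± 0.33, so its sign carries little weight. Of 12 LEA and dehydrin genes, M17 fell from 3092 ± 956 to 929 ± 889 (-2.07 ± 0.36, adjusted p = 0.0128), and the other 11 did not pass. Adjusted over the list alone, 1 rose and 3 fell, and the list's median of -0.25 did not pass (adjusted p = 0.0611). M17 read 2255 on pkl array 4 and 414 to 623 on the other 3 pkl arrays. None of 4 seed storage and oil body genes passed, also adjusted over the list alone, with a median of 0.28 (adjusted p = 0.276). That list holds 22 genes, of which only these 4 had a named probe set. None of 7 photosynthesis genes passed (1 adjusted over the list alone, adjusted p = 0.0611 for the list). Of 5 expansin and xyloglucan endotransglucosylase genes only XTH33 passed (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.477 for the list).

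In all, 64 probe sets were higher and 25 lower in pkl without uniconazole, 19 and 10 of them named, and 814 had an unadjusted p under 0.05 against 337 by chance. These counts rested on single arrays: 0 passed without wild type 1, wild type 4 or pkl 1, 2 without pkl 3, 21 without wild type 2 and 18 without pkl 2. No probe set passed when only these 2 groups were fitted or when the statistic was not moderated, 2 passed without the filter on dim probe sets and 3 without the intensity trend. With wild type array 3 and pkl array 4 left out, an alternative chosen after seeing the data, 218 were higher and 132 lower, and 88 of the 89 original calls were among them. Every named gene lost its call in at least 7 alternatives, AT1G54730 in 20 of 30, XTH33 in 16 of 31 and AT2G44220 in 16 of 30.

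With uniconazole in both genotypes, AT1G67330 was at the floor on all wild type arrays and reached 1132 ± 308 in pkl, at least 19.4-fold higher (4.28 ± 0.59, adjusted p = 0.000251). Without uniconazole the same gene read 786, 654 and 654 on pkl arrays 1 to 3 and 76 on pkl array 4. AT1G09310 rose from 67 ± 396.5 to 1572.4 ± 307.2 (3.9 ± 0.68 with values at the floor, adjusted p = 0.00118), with 3 of 4 wild type arrays at the floor. The jacalin-related lectin gene JAL31 rose from 380.5 ± 128 to 3489 ± 989 (3.21 ± 0.58, adjusted p = 0.00158), and the peroxidase gene AT5G64120 (PRX71) from 489.2 ± 382 to 2847 ± 1112 (3.01 ± 0.57, adjusted p = 0.00281). AT4G33560 and AT2G43150 rose 7.89-fold and 7.81-fold, and AT1G13930 rose 5.74-fold (adjusted p = 0.00197, 0.000642 and 0.0046). PRK was again at the floor in wild type and at least 7.06-fold higher in pkl (2.82 ± 0.41, adjusted p = 0.000286).

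AT1G23590 was lower in pkl than in wild type with uniconazole, going from 475 ± 217 to 40 ± 90.4 (-2.58 ± 0.50, adjusted p = 0.00342), with 3 of 4 pkl arrays at the floor, and AT1G27020 from 540.2 ± 71.4 to 141.5 ± 88.4 (-2.17 ± 0.53, adjusted p = 0.0184). M17 fell from 3008 ± 593 to 933.3 ± 154 (-1.68 ± 0.36, adjusted p = 0.00785). GH3.1, of a family that joins auxin to amino acids, fell from 337.2 ± 99.3 to 119.3 ± 28.7 (-1.47 ± 0.39, adjusted p = 0.0301). AT2G23100 and AT2G31990 were at the floor on all pkl arrays, at least 3.82-fold and at least 2.69-fold lower (adjusted p = 0.0309 and 0.00368). AT4G19390 (-1.68 ± 0.44) and AT2G37310 (-1.59 ± 0.43) also fell, with adjusted p of 0.0254 and 0.0305.

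Of the 4 tested seed storage and oil body genes, 2 were higher in pkl than in wild type with uniconazole (3 adjusted over the list alone), all 4 were positive and the median was 1.1 (camera adjusted p = 0.000218, and adjusted p = 0.00884 with an estimated correlation). AT1G03890, among these 4, was at the floor in wild type with uniconazole (mean log2 5.83) and near it in pkl (6.21), so its sign carries little weight. AT2G28490 and AT4G36700 belong to the cupin family, which includes the seed storage globulins. AT2G28490 rose from 836.4 ± 144 to 1993 ± 73.1 (1.27 ± 0.18, adjusted p = 0.00028) and AT4G36700 from 357.7 ± 227 to 1206 ± 205.0 (1.92 ± 0.40, adjusted p = 0.00617). The oleosin gene OLEO3, whose protein coats oil bodies, differed by 0.93 ± 0.28 and did not pass (adjusted p = 0.0586).

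Of 3 heat shock genes, AT1G53540 (2.06 ± 0.43) and AT2G29500 (1.67 ± 0.47) rose (2 adjusted over the list alone), with a list adjusted p of 0.00887, and adjusted p = 0.103 with an estimated correlation. The other, ATHSP22.0, lay at the floor in wild type with uniconazole (mean log2 5.83) and near it in pkl (6.24). Among the 12 LEA and dehydrin genes M10 (1.09 ± 0.25) and COR47 (0.58 ± 0.16) rose and M17 fell (3 higher and 1 lower adjusted over the list alone). That list did not move one way (median 0.20, adjusted p = 0.551). XTH33 rose (1.24 ± 0.27) while EXPA15, an expansin that loosens cell walls, fell from 14786 ± 3307 to 7289 ± 1694 (-1.02 ± 0.22). Of the 5 genes of their list 1 was higher and 1 lower, also adjusted over the list alone (adjusted p = 0.503). Of 7 photosynthesis genes PSAE-1 rose (0.77 ± 0.22), a subunit of photosystem I, although its other 2 probe sets did not (-0.03 and -0.17). Adjusted over the list alone 2 rose, and the list's adjusted p was 0.0361, with adjusted p = 0.243 with an estimated correlation. Neither PRL (0.56) nor HIS4 (0.64), the 2 cell cycle genes tested, passed, while both did adjusted over the list alone. The probe set of HIS4 is of a type that can also detect close relatives in the gene family. Their list had adjusted p = 0.0491, and adjusted p = 0.115 with an estimated correlation.

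In all, 245 probe sets were higher and 118 lower in pkl with uniconazole, 93 and 42 of them named, and 142 and 37 changed at least 2-fold. The counts fell to 139 higher and 53 lower without pkl with uniconazole 1, to 148 and 69 without pkl with uniconazole 3, and to 165 and 59 without wild type with uniconazole 3, and without the intensity trend to 144 and 46. The calls of AT1G67330, AT1G09310, AT5G64120, AT4G33560, AT2G43150, PRK, AT1G23590, AT2G28490 and AT4G36700 held in every alternative in which they were tested, whereas that of PSAE-1 was lost in 20 of 30. Those of COR47, AT2G29500, AT2G23100 and AT2G37310 were lost in 12 of 31, 12 of 30, 12 of 30 and 11 of 30, and the other named calls in at most 8. The log2 ratio of 3' to 5' GAPDH signal, a measure of RNA quality, was 0.59, 1.06, 1.26 and 1.75 on arrays 1 to 4 of wild type with uniconazole, and 0.52 to 0.78 in pkl with uniconazole. A contribution of RNA quality to this comparison, to uniconazole in wild type (0.54 to 0.98 without it) and to the interaction was not tested and is not excluded.

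The 2 genotype comparisons share no array, but both come from the same fit and use the same variance estimate for each probe set. They shared 57 probe sets that were higher in both, where independent lists of these sizes would share 2.32. They also shared 13 that were lower in both against 0.437, and 0 passed in opposite directions. A probe set with a low variance estimate is favoured in both lists, so the lists are not independent. The expected counts of 2.32 and 0.437 are therefore too low a baseline to weigh the overlap. The direction with uniconazole was the same for 85 of the 89 probe sets called without it. Of the 363 called with it, 342 had the same direction without it. Across all tested probe sets, which are not independent replicates, fold changes correlated with a Pearson r of 0.40 and a Spearman rho of 0.30. The correlation was 0.18 with the floor at the 20th percentile and 0.60 at the 45th, and the shared count fell to 0 wherever no probe set passed without uniconazole. AT1G53540, PRK, XTH33, AT1G62480, AT1G62500, AT1G09750, AT4G20860, AT2G25980 and M17 were among the 22 named probe sets past the threshold in both, of which 19 were higher and 3 lower.

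**Figure D2:**
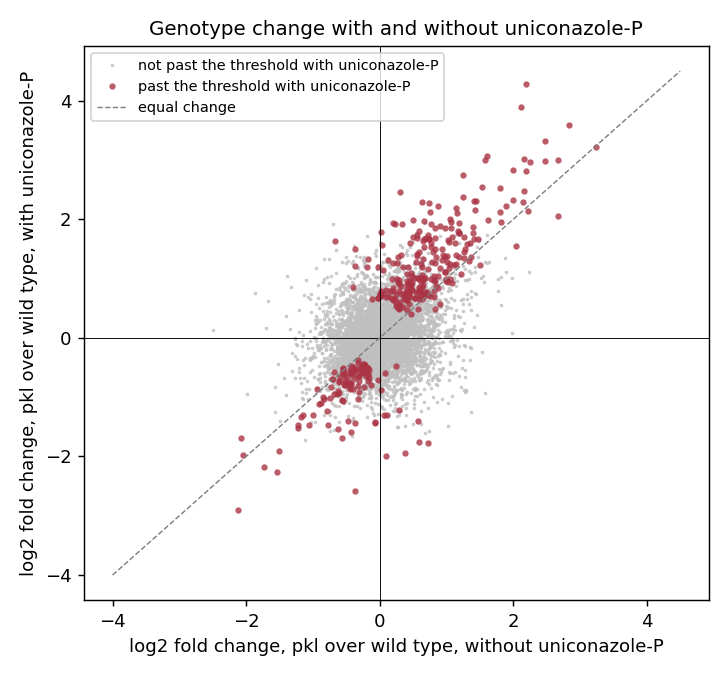
Log2 fold change of pkl over wild type without (horizontal axis) and with uniconazole (vertical axis), each point 1 of 6749 probe sets. The 363 past the threshold with uniconazole are in red, 342 of them with the same sign on both axes, and the dashed line marks equal change.

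Few probe sets passed for uniconazole in wild type, a comparison in which 16% of 1.5-fold and 50% of 2-fold simulated changes passed. None of the named genes passed. The smallest p among them belonged to AT4G01150, encoding the thylakoid protein CURT1A, at 4489 ± 845 without and 6973 ± 908 with the inhibitor (0.64 ± 0.13, adjusted p = 0.0917). Next came AT4G25260 (-0.69 ± 0.15, adjusted p = 0.11), AT2G31990 (1.26 ± 0.28, adjusted p = 0.11) and the dehydrin gene COR47 (-0.72 ± 0.16, adjusted p = 0.112). Unnamed probe sets A and B (no gene is given for them), chosen after their values were seen because they were the only calls, rose. Probe set A went from 170.8 ± 114 to 911.4 ± 157 (2.60 ± 0.32, adjusted p = 0.000489) and probe set B from 2999 ± 414 to 5033 ± 874 (0.74 ± 0.13, adjusted p = 0.0364). Of the lists none passed, and the lowest adjusted p, 0.0838, belonged to seed storage (median 0.51, 3 of 4 positive, 0 genes past also over the list alone) and to expansins and xyloglucan endotransglucosylases (median -0.26, 1 lower adjusted over the list alone). The 12 LEA and dehydrin genes had a median of 0.04 and a mean of -0.11, which differ in sign (adjusted p = 0.884).

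In wild type limma thus called 2 probe sets higher and 0 lower, with 464 at an unadjusted p under 0.05 against 337 by chance, and the unmoderated statistic called 2 and 0, of which 1 was among these calls. The call of probe set B was lost in 15 of 30 alternatives and that of probe set A in 2 of 30, and 0 passed when only the 2 groups were fitted.

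In pkl, uniconazole raised transcripts of the seed storage and oil body list. Of the 4 tested genes 3 rose, also adjusted over the list alone, and the median was 1.32 (camera adjusted p = 1.28e-08, and adjusted p = 0.000406 with an estimated correlation). AT4G36700 went from 215 ± 60.2 to 1206 ± 205.0, 5.73-fold (2.52 ± 0.40, adjusted p = 0.00172). AT2G28490 went from 819 ± 138 to 1993 ± 73.1 (1.3 ± 0.18, adjusted p = 0.000432), and OLEO3 from 1465 ± 619 to 3544 ± 823 (1.35 ± 0.28, adjusted p = 0.0238). The fourth gene of the list, AT1G03890, a cruciferin-type storage globulin, lay near the floor, differed by 0.07 ± 0.30 and did not pass. Outside the list, AT1G04350 rose from 5 ± 48.2, with 3 of 4 arrays at the floor, to 207.8 ± 85.8 (1.68 ± 0.30, adjusted p = 0.00574).

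**Figure D3:**
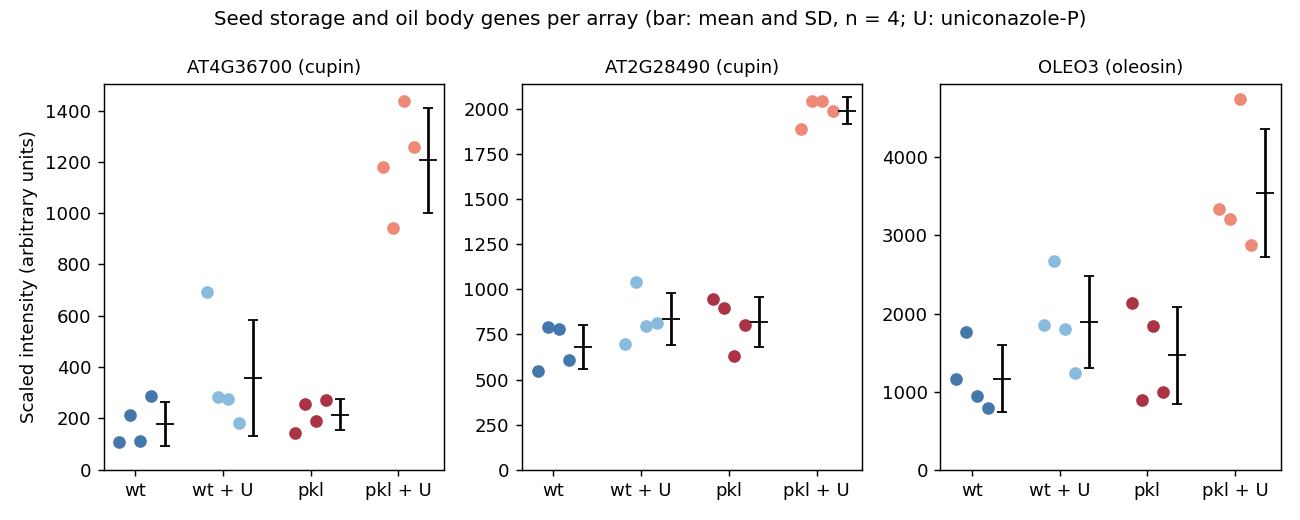
Scaled intensity (vertical axes, arbitrary units) of AT4G36700, AT2G28490 and OLEO3 on each array (points) in the 4 groups, with the mean and SD of each group (n = 4) as bars, U standing for uniconazole-P. Every array of pkl with uniconazole lies above every array of the other 3 groups, from 944 for AT4G36700, 1890 for AT2G28490 and 2883 for OLEO3.

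Of 12 LEA and dehydrin genes, AT3G17520 rose in pkl with the inhibitor (0.73 ± 0.15, adjusted p = 0.0202), and 3 rose and 1 fell adjusted over the list alone. The list's median was 0.42 with 10 of 12 positive (adjusted p = 0.00185, and adjusted p = 0.205 with an estimated correlation). No expansin, photosynthesis, heat shock or cell cycle gene passed in pkl (list adjusted p = 0.0893, 0.298, 0.528 and 0.601), nor did any adjusted over the list alone. In all, 30 probe sets were higher and 3 lower, 9 and 0 of them named, with 487 at an unadjusted p under 0.05. Without moderation 15 were higher and 0 lower, without the intensity trend 19 and 1, and without the filter on dim probe sets 15 and 0. OLEO3 lost its call in 11 of 31 alternatives, AT3G17520 in 9 of 31, and AT4G36700 and AT2G28490 in 0. The calls in wild type, unnamed probe sets A and B, also passed in pkl. Of the 30 probe sets higher in pkl, 26 were positive in wild type, and over all 33 the median change was 1.18 in pkl and 0.39 in wild type. The 33 were selected by passing in pkl, which raises their median there, so these medians do not show a weaker response in wild type. Uniconazole's fold changes in the 2 genotypes correlated across probe sets with a Pearson r of 0.06 and a Spearman rho of 0.04, and r was 0.20 with the floor at the 45th percentile.

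The interaction asks whether the response to uniconazole differed between the genotypes. The seed storage and oil body genes responded more in pkl as a list: all 4 differences were positive, with a median of 0.82 (camera adjusted p = 0.00123, and adjusted p = 0.0187 with an estimated correlation). Over all probe sets 0 of the 4 passed singly, and adjusted over the list alone 2 did. The differences were 1.58 ± 0.57 for AT4G36700, 1.0 ± 0.25 for AT2G28490, 0.63 ± 0.40 for OLEO3 and 0.26 ± 0.42 for AT1G03890. The last lay at or near the floor in all 4 groups (mean log2 5.83 to 6.21), so its sign carries little weight. The differences of the 12 LEA and dehydrin genes were all positive, with a median of 0.37 (adjusted p = 0.00594, and adjusted p = 0.419 with an estimated correlation), and 0 passed singly, also adjusted over the list alone. GSTF3, a glutathione S-transferase, was the named gene that passed (1.58 ± 0.27, adjusted p = 0.0269). It went from 1495 ± 356 to 1035 ± 137 in wild type and from 1149 ± 220.0 to 2397 ± 364 in pkl. Its probe set is of a type that can also detect close relatives in the gene family, so the gene is uncertain. Unnamed probe set C, chosen after its values were seen, also passed (1.27 ± 0.20, adjusted p = 0.0185), rising from 3846 ± 741 to 9037 ± 891 in pkl and reading 5051 ± 589 and 5007 ± 808 in wild type.

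Limma called 2 probe sets higher and 0 lower for the interaction, with 362 at an unadjusted p under 0.05 against 337 by chance, and the unmoderated statistic called 0 and 0. GSTF3 lost its call in 15 of 30 alternatives and probe set C in 10 of 29, and neither passed with the array number as a block. No probe set passed without wild type 1, wild type 3, pkl 1, or pkl with uniconazole 1 or 2. The mean genotype effect and the mean uniconazole effect correlated at -0.04 (Spearman -0.05) across probe sets.

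The remaining lists held few genes on this array. ICL and AIM1, of lipid mobilisation and the glyoxylate cycle, did not pass in any comparison (list adjusted p of 0.828 without and 0.78 with uniconazole between the genotypes), nor did the auxin response genes IAA18 and IAA20 (0.449 and 0.78). Adjusted over the list alone these 4 genes did not pass either. A single gene was tested in 4 lists, and none passed in any of the 5 comparisons: KIN2 for ABA or cold response, SLY1 for gibberellin signalling, EIN3 for ethylene and DFR for flavonoid synthesis. Between the genotypes with uniconazole, KIN2 differed by -0.76 ± 0.29, SLY1 by 0.48 ± 0.21, EIN3 by -0.01 ± 0.15 and DFR by 0.16 ± 0.31. With 1 gene tested, adjusting over the list alone leaves limma's p unadjusted. That p was 0.029 without and 0.0164 with uniconazole for KIN2, lower in pkl, and 0.0317 for SLY1, higher in pkl with uniconazole. Adjusted over all probe sets these were 0.327, 0.148 and 0.219. No gene was tested in the lists of embryo identity regulators, gibberellin metabolism, brassinosteroid synthesis and perception, Polycomb and CHD3 factors, floral and meristem genes, root markers, or endosperm and seed coat markers.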

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

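The 6 tests of explanations in this part were chosen after the results they address had been seen. Single arrays were compared with the other 3 of their group by the size of the gap, a measure that chance exceeds in about 1 of 20 groups. It was exceeded in 5 of 100 combinations of named gene and group, and in 5 of 24 combinations of array measure and group.

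The genotype score of pkl array 4, 0.49, lay far from the 0.86 to 0.91 of the other untreated pkl arrays, and wild type array 3 scored 0.56. By this score a full exchange of their labels is argued against. The 0.56 of wild type array 3 lay below the lowest other pkl array (0.86), and the 0.49 of pkl array 4 above the highest other wild type array (0.16). The first principal component also placed both between the genotypes, with wild type array 3 at 4.0 and pkl array 4 at -4.1. The other untreated arrays lay at -18.7 to -16.9 in wild type and 18.5 to 21.5 in pkl. Regrouping the untreated arrays with these 2 exchanged gave 205 calls, against 89 as labelled. That count cannot tell a full exchange from 2 intermediate arrays whose order is reversed, so an exchange is not excluded. A mixture of seed or RNA of the 2 genotypes stays open: with 1 mixing fraction (0.46 pkl in wild type array 3, 0.35 in pkl array 4) the residual SD was 0.40 and 0.42 on the log2 scale, within the 0.36 to 0.51 of the 6 other untreated arrays, but single genes departed from 1 fraction both ways. On wild type array 3, AT2G43150 read 8473 (pkl arrays 1 to 3 read 7688 to 16451), but AT4G33560 read 658 (2707 to 4387) and PRK -5. On pkl array 4, AT1G53540 read 417, close to the 425 to 646 of the other pkl arrays, but AT4G33560 read 460 and AT1G67330 read 76. Degraded RNA is argued against for wild type array 3, whose log2 ratio of 3' to 5' GAPDH signal (0.69) lay within those of the 6 others (0.48 to 0.98). This rests on the ratio of 1 control gene. The share of probe sets at the floor (30%, others 27.6% to 31.4%) cannot decide it, because the floor was placed at the 30th percentile of all values. For pkl array 4 degraded RNA stays open, because its ratio of 1.07 lay above those of the 6 others. Wild type with uniconazole 3 and 4 had higher ratios, 1.26 and 1.75, and scored 0.07 and 0.15. They also lay lowest on the first principal component (-29.1 and -24.3). Being wild type, they cannot show whether a high ratio moves an array toward the wild type side. The design gives no group that differs within these arrays, so no biological explanation was tested.

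Between the genotypes 363 probe sets passed with uniconazole and 89 without. The 2 arrays between the genotypes may account for much of this, since 350 passed without uniconazole and 408 with it once both were left out. These arrays were chosen because they lie between the genotypes, so a rise was partly built in, but leaving out each of the 15 other pairs of 1 wild type and 1 pkl array gave 0 to 195, with a median of 0. A larger genotype difference when gibberellin is limiting stays among the open explanations, and the interaction, which tests it probe set by probe set, called 2.

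The spiked-in bacterial control BioB5 read high on arrays numbered 2, at 7713 in wild type (others 1557 to 3895), 5353 in wild type with uniconazole (others 1654 to 2141), 7702 in pkl (2006 to 2775) and 7849 in pkl with uniconazole (1440 to 1980). CreX3 read 225056 on pkl array 2 and 103417 to 106642 on the other 3, and it was also highest on array 2 in wild type (242066, others 84905 to 165967), in wild type with uniconazole (198790, others 88982 to 114401) and in pkl with uniconazole (241323, others 78052 to 110389). Arrays were left out by number to ask whether a shared batch of hybridisation also sets the genotype calls with uniconazole. The counts cannot decide this. Each number occurs once in each group, so a shift shared by a number would add equally to both genotypes. Without the 2 uniconazole arrays numbered 2, 215 of the original 363 calls stayed, and without those numbered 1, 3 or 4, 170, 128 and 206 did. Without all 4 arrays numbered 2, 257 passed with uniconazole, 203 of them original calls, and 0 passed without it, so an effect on single calls stays open. Whether those arrays were handled together stays open, and no biological explanation was tested.

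Among the named genes, AT1G53540 read 646 on pkl array 1 and 417 to 430 on the other 3. M17 read 2255 on pkl array 4 and 414 to 623 on the others. PRK read 208 on array 4 of pkl with uniconazole and 488 to 516 on the others. In wild type with uniconazole, array 4 read 190 for GH3.1 (others 365 to 398) and 6333 for probe set B (others 4462 to 4727).

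The response to uniconazole differed between the genotypes by the interaction test for GSTF3 (1.58 on the log2 scale, adjusted p = 0.0269) and for probe set C (1.27, adjusted p = 0.0185). Neither passed with the array number as a block. The median difference was 0.82 for the seed storage and oil body list (adjusted p = 0.00123, with all 4 genes positive, among them AT1G03890 at or near the floor) and 0.37 for the LEA and dehydrin list (adjusted p = 0.00594, with all 12 positive, and adjusted p = 0.419 with an estimated correlation).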

How the results depend on the processing

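The alternatives that leave out wild type 3 and pkl 4 together, or the 4 arrays numbered 2, and the floor at the 70th percentile, were chosen after seeing the data. Counts are given as higher/lower. Of 46 calls of named genes, 1092 of 1401 recomputed values (77.9%) kept the call, 309 lost it and none changed sign, and of the 4 named values that had not passed, 8 recomputed values did. The seed storage list kept its call in all 25 alternatives for pkl against wild type with uniconazole (adjusted p from 7.13e-05 to 0.00884), for uniconazole in pkl and for the interaction. Over all lists, 884 recomputed values stayed on their side of the threshold with the same sign, 30 lost and 20 gained a call, and 51 that had not passed changed sign. Between the genotypes with uniconazole, the cell cycle list lost its call in 16 of 25 alternatives and the photosynthesis list in 5 of 25. For the interaction the LEA and dehydrin list lost it in 6 of 25. Leaving the values unscaled changed no count, which says nothing about stability because the deposited arrays already share a trimmed mean. About 30% of each array lay at the floor, but the floor was placed at the 30th percentile of all values. That share is therefore set by the method and does not measure how dim the signal was.

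Without uniconazole, pkl against wild type gave 2/0 with no filter (893 at an unadjusted p under 0.05), 3/0 without the intensity trend (762), 0/0 with only the 2 groups in the fit (771), 0/0 without moderation (796), 196/139 with array weights, 18/9 with 1 probe set per gene and 39/13 at 2-fold. It gave 218/132 without wild type 3 and pkl 4, 0/0 without the arrays numbered 2 (761), and 41 lower with the floor at the 70th percentile. With uniconazole it gave 144/46 without the trend, 84/36 with 1 probe set per gene, 151/68 without moderation and 142/37 at 2-fold. Uniconazole in wild type gave 1 higher with quantile normalization, 1 lower with no filter, 0 higher with only the 2 groups (389 unadjusted) or 1 probe set per gene (167), 1 higher at 2-fold, 4/1 without the arrays numbered 2 and 1 lower at the 70th percentile. Uniconazole in pkl gave 5 lower at the 45th percentile, 15/0 with no filter, 19/1 without the trend, 1 lower with only the 2 groups, 57/21 with array weights, 8/0 with 1 probe set per gene, 15/0 without moderation, 0 lower at 2-fold, 16/1 without the arrays numbered 2 and 47/12 at the 70th percentile. The interaction gave 0 higher with no filter (400 unadjusted), without the trend (354), without moderation (355) and without the arrays numbered 2 (536), 1 lower with array weights, 1 higher with 1 probe set per gene, 4 higher without wild type 3 and pkl 4, and 7 higher at the 70th percentile. Fewer probe sets tested or fewer arrays are part of some of these alternatives, and otherwise the cause was not tested.

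The genotype comparisons shared 2 calls with no filter, 3 without the trend, 0 with only the 2 groups, 167 with array weights, 20 with 1 probe set per gene, 0 without moderation, 204 without wild type 3 and pkl 4, and 0 without the arrays numbered 2. Their correlation was 0.18, 0.60 and 0.73 with the floor at the 20th, 45th and 70th percentile, and the cause was not tested. The uniconazole comparisons shared 1 with quantile normalization, no filter, no trend, no moderation or the arrays numbered 2 left out, and 0 with only the 2 groups or 1 probe set per gene. Their correlation was 0.20 and 0.30 at the 45th and 70th percentile and -0.02 without the arrays numbered 2.

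With each array left out in turn, pkl against wild type without uniconazole ranged from 0 to 145 higher and 0 to 103 lower. It was 0/0 without wild type 1, wild type 4 or pkl 1 (650, 630 and 671 unadjusted), 2/0 without pkl 3, 18/3 without wild type 2, 16/2 without pkl 2, 136/46 without wild type 3, 145/103 without pkl 4, 92/43 without wild type with uniconazole 4, and 42/15 and 37/13 without pkl with uniconazole 2 and 4. With uniconazole it ranged from 139 to 263 higher and 53 to 129 lower, with 139/53, 148/69 and 165/59 without pkl with uniconazole 1 and 3 and wild type with uniconazole 3. Uniconazole in wild type ranged from 1 to 4 higher and 0 to 1 lower, uniconazole in pkl from 21 to 37 and 0 to 7, and the interaction from 0 to 4 and 0 to 1. The interaction had 0 higher without wild type 1 or 3, pkl 1, or pkl with uniconazole 1 or 2, 1 without wild type 4, wild type with uniconazole 2 or 4, or pkl with uniconazole 4, and 4 without pkl 4. In wild type uniconazole had 4 higher without wild type 2, wild type with uniconazole 1 or pkl 2, and 1 without wild type 1 or 4, pkl 3 or any array of pkl with uniconazole. In pkl it had 0 lower without wild type 1, wild type with uniconazole 3, pkl 3, or pkl with uniconazole 1 or 3, 1 without wild type with uniconazole 2 or pkl with uniconazole 2 or 4, and 7 without wild type with uniconazole 4. The shared genotype calls ranged from 0 to 152 (0 without wild type 1 or 4 or pkl 1, 2 without pkl 3, 20 and 16 without wild type 2 and pkl 2, 126 and 152 without wild type 3 and pkl 4, 42 and 40 without pkl with uniconazole 3 and 4) with r from 0.33 to 0.44, the shared uniconazole calls from 1 to 3 with r from 0.03 to 0.08, and the correlation of the main effects from -0.16 to 0.08.

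The labels give the array numbers no meaning, and the arrays were not treated as paired: deviations from the group means correlated at -0.09 to 0.12 over the 24 same-number pairs (median 0.02, against -0.01 for other pairs), 4 of them over 0.1, and 7 of 16 arrays correlated best with an array of their own number in another group. With the number as a replicate block the counts were 80/31 and 234/120 between the genotypes without and with uniconazole, 2/0 and 29/2 for uniconazole in wild type and pkl, and 0/0 for the interaction (365 unadjusted).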

Other observations

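The genes in this part were chosen after their values were seen. JAL31, a jacalin-related lectin, was also higher in pkl without uniconazole (3.24 ± 0.58, adjusted p = 0.0128), but its groups overlapped because it read 1053 on wild type array 3 and 802 on pkl array 4. The related lectin JAL34 was higher in pkl when uniconazole was present (1.70 ± 0.33, adjusted p = 0.00294) and differed by 1.27 ± 0.33 without it (adjusted p = 0.059). NAI1, a transcription factor needed for endoplasmic reticulum bodies, rose in both comparisons (1.06 ± 0.26 and 1.0 ± 0.26, adjusted p = 0.0432 and 0.0248), as did WLIM2a (1.37 and 1.36, adjusted p = 0.0363 and 0.012), a protein that binds actin. The peroxidase gene AT5G64100 rose by 0.88 and 0.85 (adjusted p = 0.0306 and 0.0118). MSRB5, a methionine sulfoxide reductase, fell in both (-1.18 and -1.34, adjusted p = 0.0411 and 0.00645), and so did the U-box ubiquitin ligase gene PUB19 (-0.94 and -0.86, adjusted p = 0.048 and 0.0344).

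AT2G25890, an oleosin family gene outside the fixed list, differed between the genotypes by 0.02 ± 0.19 without uniconazole and by 0.79 ± 0.19 with it (adjusted p = 0.0135). It rose with uniconazole in pkl (0.82 ± 0.19, adjusted p = 0.0473), while in wild type the difference was 0.05 ± 0.19. The difference between these responses, 0.77 ± 0.26, did not pass (adjusted p = 0.821). The LEA genes M17 (AT2G41260) and M10 (AT2G41280) differed between pkl and wild type in opposite directions when uniconazole was present, by -1.68 and 1.09.

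Other splits of the same arrays were counted for each comparison, the real one included, and all but the first of these tests were planned before their results were seen. For pkl against wild type without uniconazole, 2 of 35 splits gave as many calls (share 0.057), so chance was not excluded by this measure. The real split gave 89 and the highest other gave 205, several times the 11 of the next one. That split exchanges wild type array 3 and pkl array 4, which points to a structure of the samples and bears on the exchange of labels discussed above. With uniconazole, 1 of 35 splits, the real one with 363, gave as many, the highest other giving 1. This share of 0.029 is under 0.05 and is the smallest that 35 splits can give. For uniconazole in wild type 4 of 35 splits gave as many as the real 2, the highest other giving 8, so chance was not excluded. For uniconazole in pkl 1 of 35 did, the real one with 33 against at most 1, again a share of 0.029. For the interaction 3 of 100 drawn regroupings gave as many as the real 2, the highest other giving 3. That share is under 0.05, but it was not adjusted for the number of comparisons, and the highest regrouping gave more calls than the real data. Chance is therefore not excluded for the interaction. With the array number as a block in the fit, 0 probe sets passed for the interaction. The 2 calls therefore depend on the fit without that block.

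A hypothesis written before its result was seen held that genes near PKL may differ because they are linked to the mutated locus. Of 129 distinct named genes called with uniconazole, 9 (6.98%) lay among the 500 nearest annotated genes on each side of PKL, against 192 of the 2943 genes tested (6.52%). The 1-sided exact Fisher test gave p = 0.468. With 9 genes the test is too coarse to exclude linkage for single genes.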
